A study of Danio rerio with 6 samples.

How the data were processed

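Poly(A) RNA was measured in 6 pools of whole zebrafish (strain AB) at 96 h post fertilization (hpf). Per the labels' protocols, each pool held 18 to 20 eleutheroembryos, the free-swimming stage that still feeds on yolk. The chorion was removed by hand at 24 hpf, and the animals then stayed until 96 hpf in glass vials of 5 with a DMSO vehicle at 0.05% v/v, alone or with 4500 µg/L of PCB-11. There were 3 DMSO pools and 3 PCB-11 pools, with the group and replicate number taken from the sample titles. Libraries were directional and were read as short single ends, per the labels' protocols. The labels do not say whether pools came from separate clutches or exposures, so the p-values measure the spread between these pools, part of which may be technical.

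The deposited values are whole-number read counts per gene symbol, 1 table per pool, made by the authors before deposit. The submitters' processing notes name the genome build danRer7 and Cufflinks, without a role or version. The aligner, the counting program, its strand setting and the annotation are not given in the sources used here. The tables cover 14791 gene symbols, and each closes with 2 rows that name no gene, for reads outside annotated genes and for ambiguous reads. Those rows stayed out of library sizes and tests. Reads outside genes made up 31.4% to 39.1% of all counts in a pool, and ambiguous reads 0.379% to 0.429%. Near-identical copies, such as the gamma crystallins and the fast myosins, and overlapping genes can lose or exchange reads in such counting, so single members of these families are uncertain.

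Counts assigned to genes ranged from 15705712 to 20479751 per pool. The 95% Wilson interval of the share of reads outside genes was at most 0.0375 percentage points wide in any pool; such intervals cover counting error only, since the reads carry no molecular identifiers. In total 12960 genes passed the default expression filter of edgeR and were tested, and 1831 were not.

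Groups were compared with edgeR 4.0.16 in R 4.3.3: TMM scaling, robust dispersion and quasi-likelihood fits with group as the only term, and two-sided quasi-likelihood F tests. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are PCB-11 minus DMSO, with standard errors derived from the F statistic. Levels are library-scaled counts in the usual CPM unit, after TMM scaling, as mean ± SD over 3 pools. The biological coefficient of variation common to all genes was 13.3%. The test was tried on simulated counts with the means and library sizes of these pools and 200 changed genes among 12907 genes tested. It recovered 47.8% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 92.4% of those changed 3-fold, and 8.05% of its calls were false. Simulated genes varied independently of one another, without the structure shared by genes across the real pools. The 200 planted changes also ease the adjusted threshold. These shares therefore hold for the simulated counts alone. For the real counts the recovered shares may be too high, and the share of false calls may be higher than simulated.

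In all, 38 gene lists were fixed before the data were examined, covering xenobiotic and stress responses, metabolism, hormone axes, the cell cycle, the clock and markers of tissues and cell types. Of 1120 list entries, 993 matched a symbol in the tables, 45 of them through a synonym in the RefSeq table of assembly GRCz12tu, which served for names alone. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01. The same lists were tested with a correlation estimated per list and with fry. Members were counted past the threshold over all genes tested and adjusted over the list alone.

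The genes named in the text follow a rule fixed before the data were examined. It takes, in each direction, the called genes of at least 1 in mean log2 CPM whose groups do not overlap, and then up to 6 further genes of that level with the smallest p, said not to pass; every tested member of the aryl hydrocarbon receptor list; the 4 members with the smallest p in each called list; and the 5 genes with the smallest p. Genes named outside this rule were chosen after their values were seen, and the text says so where they stand.

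Alternatives fixed in advance were RLE, upper-quartile and plain library-size scaling, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, a fit without robust dispersion, a 1.5-fold minimum, the replicate number as a block, and leaving out each pool in turn. Sample weights, and a block that parts the pools by their macrophage list, were added after seeing the data. Figures were drawn with matplotlib 3.10.9. No coordinates are given, because the tables hold none and no annotation of danRer7 was used here.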

Results

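Gene counts were analysed from 6 pools of whole zebrafish at 96 hpf, of which 3 had been kept in DMSO and 3 in 4500 µg/L PCB-11 from 24 hpf. PCB-11 is 3,3'-dichlorobiphenyl, a lightly chlorinated member of the polychlorinated biphenyls. Counts assigned to genes were 17811432, 18808853 and 19681843 in DMSO replicates 1, 2 and 3, and 18578645, 15705712 and 20479751 in PCB-11 replicates 1, 2 and 3. Between 13843 and 13943 genes had at least 1 count in a pool. The comparison asked which transcripts differed after exposure through late embryonic development, and whether targets of the aryl hydrocarbon receptor, the ligand-activated factor through which several PCBs act, were among them.

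The pools differed from one another as much within the exposed group as between the groups. Log2 CPM correlated across genes with a mean r of 0.992 for pairs of DMSO pools, 0.983 for pairs of PCB-11 pools and 0.985 for pairs taken from both groups. PCB-11 replicate 2 stood apart on the first principal component, which held 43.9% of the variance, with a score of 36.9 against -16.4 to 9.31 in the other pools. That pool was lower than the mean of the DMSO pools in the median log2 value of intestine (-0.79), cartilage and bone (-0.54), skeletal muscle (-0.46) and exocrine pancreas genes (-0.63), and higher in lens (0.78) and neuron and synapse genes (0.43). The macrophage markers (11 tested, median log2 fold change -0.16, camera adjusted p = 0.738) parted the pools in another way. Their median log2 difference from the DMSO mean was -0.92, -1.19 and -0.89 in DMSO replicate 1 and PCB-11 replicates 1 and 2, and 0.65, 0.40 and 0.69 in DMSO replicates 2 and 3 and PCB-11 replicate 3. No pair of pools agreed within counting error, so no table repeated another; that the pools are separate samples rests on the labels.

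**Figure D1:**
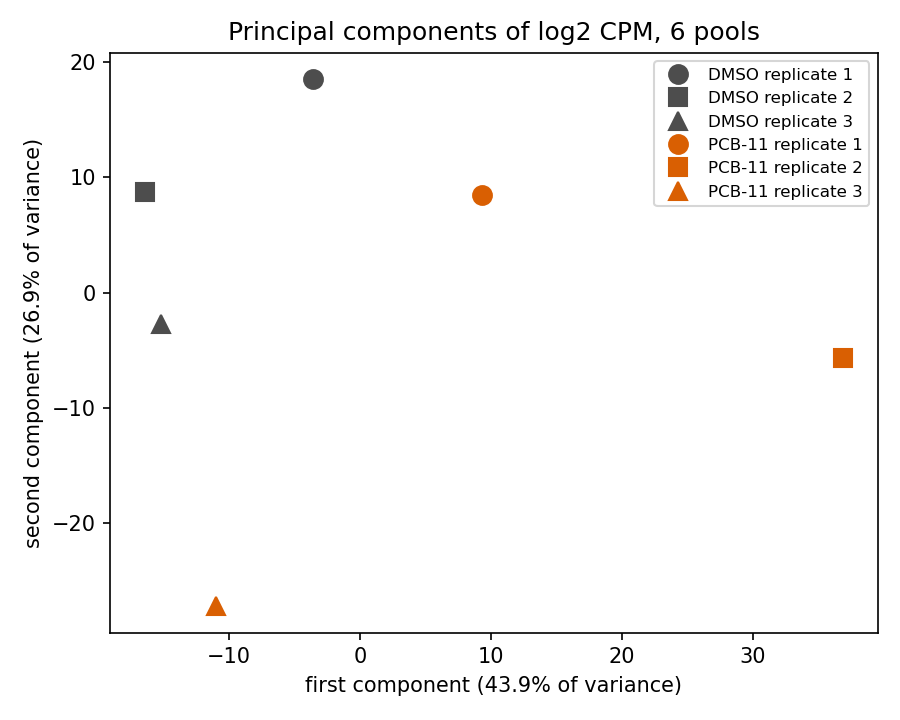
Scores of the 6 pools on the first component (x axis, 43.9% of the variance of log2 CPM) and second component (y axis, 26.9%), with DMSO in grey and PCB-11 in orange and each point a pool. PCB-11 replicate 2 lies alone at 36.9 on the first component.

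Of the 6 genes called between the groups, 5 rose in the PCB-11 pools and 1 fell. The transcript of cyp1a, a monooxygenase induced through the aryl hydrocarbon receptor, rose from 42.7 ± 2.13 to 104.7 ± 23.6 CPM (SD, n = 3 pools each), a log2 fold change of 1.29 ± 0.15 (SE). A second cytochrome P450, cyp2k6, rose from 4.96 ± 0.52 to 13.7 ± 1.94 CPM (log2 fold change 1.47 ± 0.15). Transcripts of 2 hormones rose as well: pth1a, a parathyroid hormone, from 0.47 ± 0.14 to 2.59 ± 0.31 CPM, and nppc, the precursor of C-type natriuretic peptide, from 4.44 ± 0.14 to 10.7 ± 1.74 CPM. The gene that fell was plac8.1, from 180.5 ± 16.5 to 90.3 ± 6.01 CPM (log2 fold change -0.998 ± 0.108).

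The remaining call was si:ch211-119o8.7, which rose from 5.88 ± 0.56 to 16.1 ± 3.19 CPM. Adjusted p in edgeR's quasi-likelihood test was 0.0378 for 5 of the 6 genes and 0.0468 for nppc. In each of the 6 genes all 3 PCB-11 pools lay on 1 side of all 3 DMSO pools, as a small p makes likely. The rise of pth1a rested on 7 to 11 counts per DMSO pool and 40 to 57 per PCB-11 pool, a log2 fold change of 2.47 ± 0.29. Over all 12960 genes, 1535 had an unadjusted p under 0.05 (752 higher and 783 lower), where chance alone would give 648. Parting the same pools by their macrophage markers, a split noticed in these data, gave 1662. The remaining splits into 3 and 3 gave 105 to 741. The groups did not overlap in 19.4% of genes, where chance gives 10%.

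**Figure D2:**
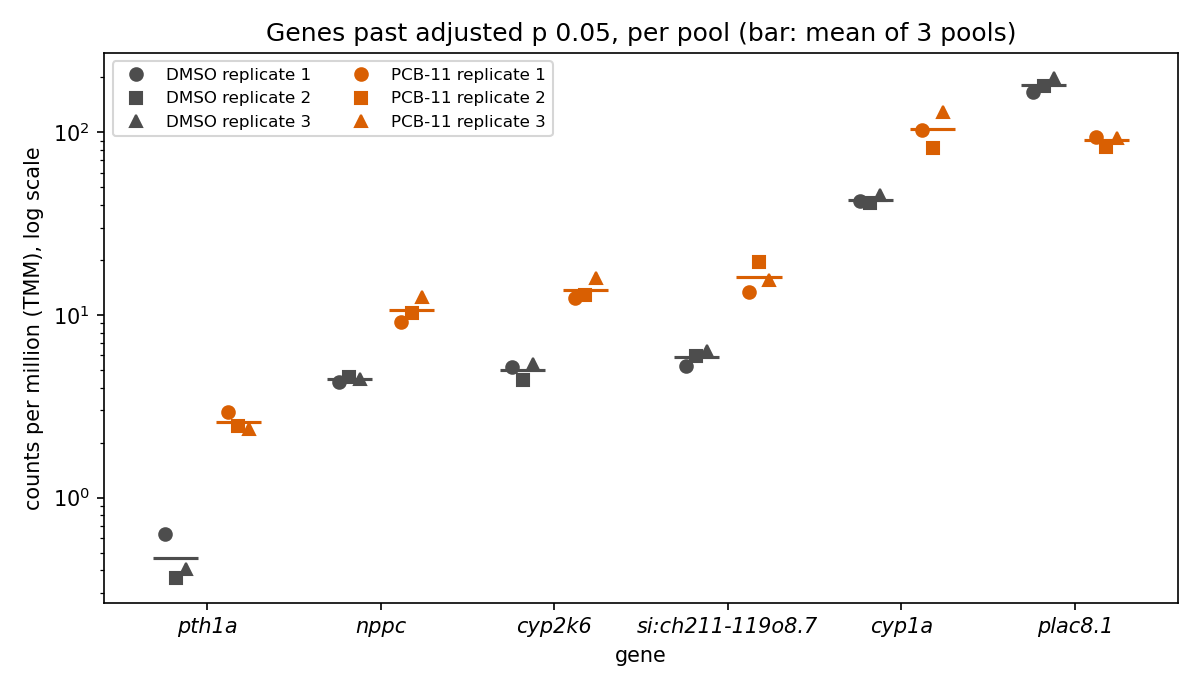
CPM on a log axis (y) of the 6 called genes (x) in each pool, with DMSO in grey, PCB-11 in orange, marker shapes for replicates 1 to 3 and a bar at the mean of 3 pools. The 3 PCB-11 values of cyp1a (82.2 to 129.3) lie above its DMSO values (40.9 to 45.0), and those of plac8.1 (83.5 to 94.5) lie below its DMSO values (165.2 to 198.0).

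The genes next in line did not pass in edgeR's test. All 12 passed in DESeq2 (adjusted p from 1.48e-09 for zgc:92590 to 0.0039 for grk1a) and none in limma-voom, and he1a and ndrg1b passed in edgeR without a filter (adjusted p = 0.0415 each). On the higher side they were the hatching enzyme gene he1a (log2 fold change 1.41 ± 0.19, from 7.12 ± 1.86 to 18.9 ± 2.01 CPM), ndrg1b (1.12 ± 0.15), the glial calcium-binding protein gene s100b (1.03 ± 0.15), zgc:194659 (0.70 ± 0.10), the urotensin-related peptide gene urp2 (1.38 ± 0.22) and the primary transcript of the muscle microRNA mir133b (1.73 ± 0.27). Their adjusted p ranged from 0.0588 for he1a to 0.12 for urp2 and mir133b in edgeR. On the lower side were zgc:92590 (-2.47 ± 0.36), the growth hormone receptor gene ghrb (-0.68 ± 0.12), si:ch211-132b12.7 (-0.57 ± 0.10), the rhodopsin kinase gene grk1a (-0.65 ± 0.12), fam46c (-0.85 ± 0.16) and zgc:154142 (-0.80 ± 0.16), with adjusted p from 0.0845 for zgc:92590 to 0.217 in edgeR. All 3 PCB-11 pools lay on 1 side of the DMSO pools in each of these 12 genes, which their choice by smallest p made likely.

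The 6 calls were sensitive to leaving out a pool. Fewer pools lower the power of the test, so a lost call need not come from the pool left out. With this limit, edgeR called 0 genes without DMSO replicate 1, DMSO replicate 3 or PCB-11 replicate 1 (1050, 988 and 1702 genes at an unadjusted p under 0.05). It called 1 gene, zgc:92590 and none of the 6, without DMSO replicate 2. That pool was the lowest control for zgc:92590, at 6.88 CPM against 12.15 and 19.41 in DMSO replicates 1 and 3. There were 7 calls, 4 of them shared, without PCB-11 replicate 2, and 184, with all 6, without PCB-11 replicate 3. Upper quartile scaling ended the calls of cyp1a and nppc (adjusted p = 0.0565 each; over all alternatives 2.07e-10 to 0.285 for cyp1a and 7.72e-07 to 0.285 for nppc). Log2 fold changes moved less than these adjusted p. Over the alternatives they were 1.12 to 1.44 for cyp1a, 1.35 to 1.54 for cyp2k6 and 1.13 to 1.36 for nppc. They were 2.32 to 2.73 for pth1a, 1.26 to 1.57 for si:ch211-119o8.7 and -1.06 to -0.93 for plac8.1. DESeq2 called 110 genes and limma-voom 0 (1540 at an unadjusted p under 0.05). With the macrophage split of the pools as a block, an alternative added after seeing the data, edgeR called 7, the 6 and the egg envelope gene zp3a.2, which was chosen after its values were seen.

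In the aryl hydrocarbon receptor list, cyp1a rose and none of the other 16 tested members passed, over all genes or adjusted over the list alone. The related monooxygenase gene cyp1b1 stayed at 3.19 ± 0.57 CPM in DMSO and 3.43 ± 0.78 in PCB-11 (log2 fold change 0.10 ± 0.23), and cyp1d1 at 35.3 ± 1.25 and 36.1 ± 5.93 (0.04 ± 0.13). The receptor gene ahr2 had 116.9 ± 7.04 CPM in DMSO and 113.2 ± 13.9 in PCB-11 (-0.05 ± 0.11). Log2 fold changes were 0.19 ± 0.11 for tiparp, a receptor-induced repressor of the pathway, -0.04 ± 0.15 for the quinone reductase gene nqo1 and -0.02 ± 0.42 for the repressor gene ahrra, which had 8 to 21 counts per pool.

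Further members lay on both sides of 0. Higher values were those of zgc:173961, matched to gsta.2 (0.46 ± 0.18), ahr1a (0.29 ± 0.20), ahr1b (0.06 ± 0.20) and the glutathione transferase gene gstp1 (0.05 ± 0.12). Lower values were those of foxq1a (-0.70 ± 0.25), arnt (-0.62 ± 0.54), ugt1a1 (-0.26 ± 0.22), sult6b1 (-0.24 ± 0.13), arnt2 (-0.22 ± 0.27) and foxq1b (-0.10 ± 0.16). Adjusted over the list alone, p was 0.000248 for cyp1a and at least 0.155 for the rest (edgeR). No scaling changed the sign of a member, although leaving out single pools did for 10 members, cyp1a not among them. The log2 ratio of cyp1a to cyp1b1 was 3.71 ± 0.33 in DMSO and 4.89 ± 0.63 in PCB-11, a difference of 1.17 (exact permutation test, two-sided, p = 0.1, the smallest that 3 pools against 3 can give). The call of cyp1a largely set this outcome beforehand, and p could not fall lower, so the permutation test decides nothing. The list as a whole did not pass camera (median -0.02, mean 0.01, adjusted p = 0.837). It passed fry's test for change in either direction (adjusted p = 0.0271), as 1 of 8 lists that did.

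The further cytochrome genes cyp1c1 and cyp1c2 were listed at 0 in all 6 pools, and ahrrb had 1 to 4 counts and wfikkn1 0 to 2. A listed 0 did not separate an absent transcript from one the counting missed, since 596 genes were at 0 in every pool, among them psmd7, a subunit of the proteasome, and the replication helicase gene mcm2. The other 32 proteasome genes tested averaged at least 44.1 CPM.

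**Figure D3:**
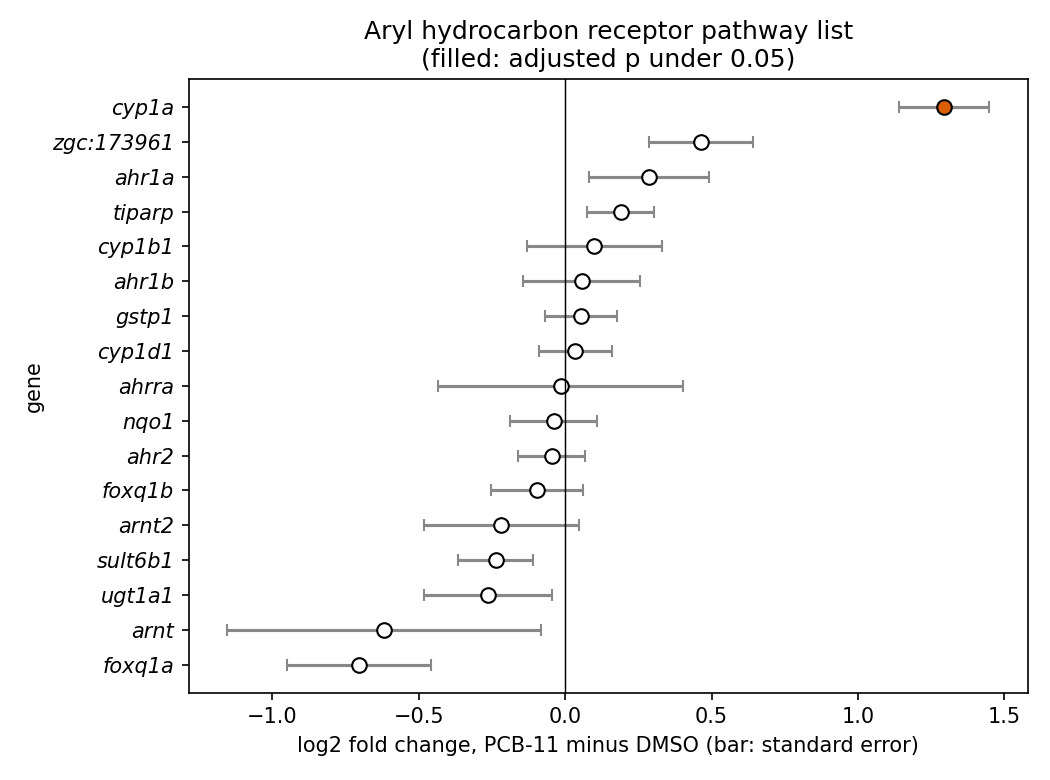
Log2 fold change, PCB-11 minus DMSO (x axis, bars are standard errors), of the 17 tested members of the aryl hydrocarbon receptor list (y axis), with filled points for an adjusted p under 0.05. The point of cyp1a at 1.29 is the filled one, and the others lie between -0.70 and 0.46.

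Among the 37 lists tested, the lens list stood farthest from the other genes. It holds crystallins, the refractive proteins of the lens, and other lens fibre proteins, and 49 of its 51 tested members had higher values in PCB-11, with a median log2 fold change of 0.51. The alpha crystallin gene cryaa had 76.3 ± 3.14 CPM in DMSO and 108.2 ± 7.93 in PCB-11. The gamma crystallin genes crygm2d1, crygm2d21 and crygm2d10 had log2 fold changes of 0.61 ± 0.14, 0.61 ± 0.14 and 0.59 ± 0.15. Pool medians were 0.38, 0.78 and 0.34 in PCB-11 replicates 1, 2 and 3, against -0.04, -0.08 and 0.14 in the DMSO replicates.

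Camera with the preset correlation called the lens list higher (adjusted p = 6.51e-21), and with an estimated correlation of 0.69 the call was lost (adjusted p = 0.989 with an estimated correlation). Adjusted over the list alone, 38 members were higher by edgeR's test. Over all genes edgeR called 0 of the 51, with 38 at an unadjusted p under 0.05, DESeq2 called 11 and limma-voom 0. The count of 38 became 0 without DMSO replicate 1 or without DMSO replicate 2, with list medians of 0.50 and 0.46. Single gamma crystallins are uncertain, since near-identical copies can exchange reads.

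The intestine list was lower by the same test with the preset correlation (camera adjusted p = 0.000505), and not with an estimated correlation (adjusted p = 0.989 with an estimated correlation). Of 21 tested members, 7 were lower when adjusted over the list alone. Levels of vil1, the microvillus protein villin, were 633.8 ± 18.7 CPM in DMSO and 386.7 ± 67.1 in PCB-11 (log2 fold change -0.71 ± 0.14). Log2 fold changes were -0.64 ± 0.15 for tm4sf4, -0.51 ± 0.13 for the peptidase gene dpp4 and -0.54 ± 0.13 for the sodium-glucose transporter gene slc5a1. The list's median was -0.24 over the groups and -0.29, -0.79 and 0 in PCB-11 replicates 1, 2 and 3.

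For the intestine list over all genes, edgeR called 0 of the 21, with 8 lower at an unadjusted p under 0.05, DESeq2 called 3 lower and limma-voom 0. The median was -0.08 without PCB-11 replicate 2 (adjusted p = 0.0147) and -0.45 without PCB-11 replicate 3 (adjusted p = 2.26e-06), and the 7 members became 0 without DMSO replicate 2, 3 without DMSO replicate 3 and 13 without PCB-11 replicate 3.

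Skeletal muscle, cartilage and bone, fatty acid oxidation and cholesterol biosynthesis were also called lower with the preset correlation, with smaller medians, and all 4 calls were lost with an estimated correlation (adjusted p = 0.989 with an estimated correlation). In the first 3 of these lists PCB-11 replicate 3 lay above 0. Skeletal muscle (50 tested, median -0.15, camera adjusted p = 0.00642) had pool medians of -0.37, -0.46 and 0.29 in PCB-11 replicates 1, 2 and 3. Its members with the smallest p were mybpc1 (-0.73 ± 0.22), myhz1.1 (-0.47 ± 0.22), smyhc3 (-0.71 ± 0.37) and actn3b (-0.46 ± 0.24), all of the contractile apparatus. Cartilage and bone (29 tested, median -0.16, adjusted p = 0.00642) had pool medians of -0.10, -0.54 and 0.02, with sp7, a bone-forming cell factor (-0.90 ± 0.30), and the collagen genes col11a1b (-0.50 ± 0.17), col10a1a (-0.38 ± 0.18) and col1a2 (-0.41 ± 0.20). Fatty acid oxidation and PPAR targets (28 tested, median -0.15, adjusted p = 0.034) had pool medians of -0.17, -0.38 and 0.07 and included the peroxisomal enzyme gene ehhadh (-0.40 ± 0.11), pparg (-0.49 ± 0.18) and acsl1b (-0.63 ± 0.22), and against them the liver fatty acid-binding protein gene fabp10a (0.46 ± 0.13).

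Cholesterol biosynthesis (22 tested, median -0.14, adjusted p = 0.0349) included the low-density lipoprotein receptor gene ldlra (-0.67 ± 0.16), the synthesis enzyme genes dhcr7 (-0.39 ± 0.12), fdft1 (-0.38 ± 0.13) and sc5d (-0.36 ± 0.15), and had pool medians of -0.31, -0.11 and -0.03. Adjusted over the list alone, ldlra was lower (adjusted p = 0.045 in edgeR) and no other member of these 4 lists passed. Over all genes edgeR and limma-voom called 0 members of the 4 lists, with 1, 2, 6 and 4 at an unadjusted p under 0.05 in muscle, cartilage, fatty acid oxidation and cholesterol, and DESeq2 called 1, in cholesterol. All 4 calls were also lost with the macrophage split of the pools as a block (adjusted p of 0.21 to 0.229 by camera, medians -0.07 in muscle, -0.12 in cartilage, -0.09 in fatty acid oxidation and -0.11 in cholesterol), under which lens (4.36e-17) and intestine (0.0128) still passed with the preset correlation. Calls also ended on leaving out PCB-11 replicate 1 (muscle 0.441, fatty acid oxidation 0.19, cholesterol 0.628), PCB-11 replicate 2 (muscle 0.365, cartilage 0.336, fatty acid oxidation 0.194) or DMSO replicate 3 (fatty acid oxidation 0.169, cholesterol 0.207), all as camera adjusted p. Medians moved to -0.055 in muscle and -0.035 in cholesterol without PCB-11 replicate 1, to -0.0065 in muscle, -0.09 in cartilage and -0.047 in fatty acid oxidation without PCB-11 replicate 2, and to -0.088 in cholesterol without DMSO replicate 3. Without PCB-11 replicate 3 they moved to -0.415 in muscle, -0.29 in cartilage, -0.27 in fatty acid oxidation and -0.22 in cholesterol. The fatty acid oxidation median was -0.108 without PCB-11 replicate 1 and -0.131 without DMSO replicate 3, against -0.147 with all pools. Over the alternatives camera and fry gave adjusted p from 1.43e-16 to 0.989 for muscle, 1.59e-05 to 0.989 for cartilage, 0.000127 to 0.989 for fatty acid oxidation, 0.00402 to 0.989 for cholesterol, 2.26e-06 to 0.989 for intestine and 2.9e-24 to 0.989 for lens.

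**Figure D4:**
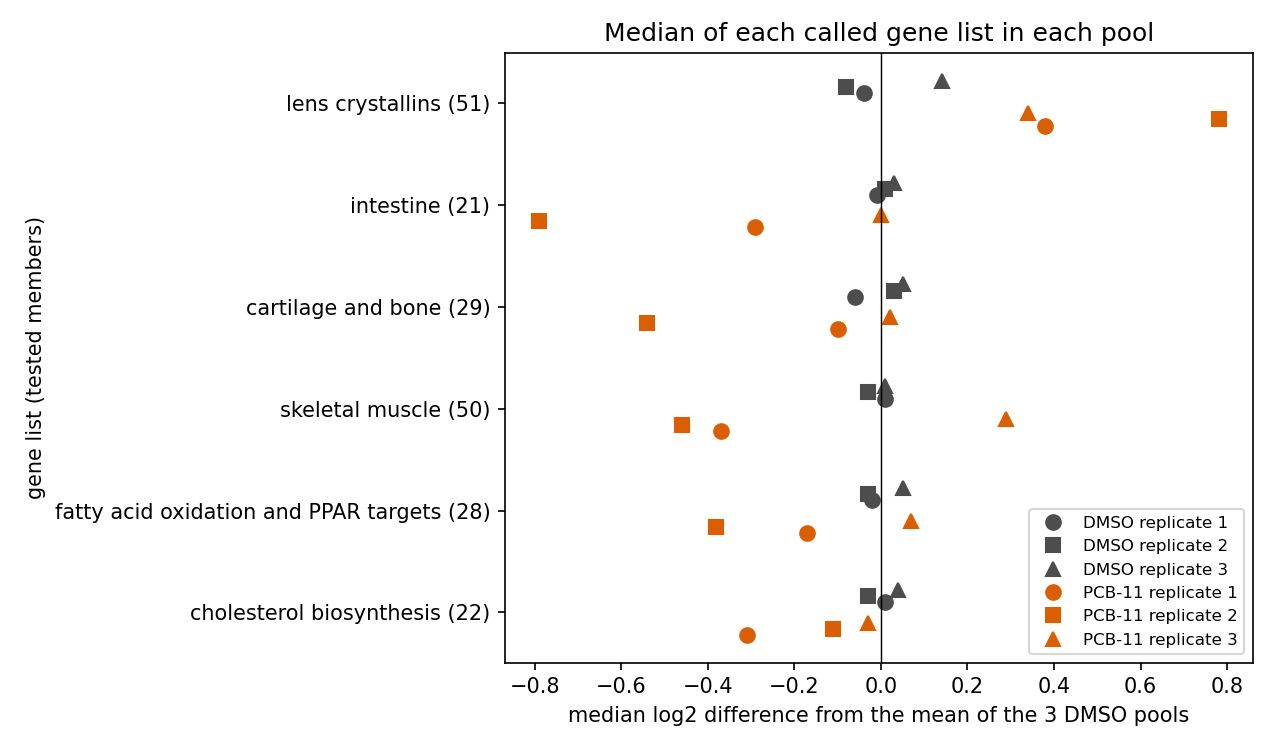
Median log2 difference from the mean of the 3 DMSO pools (x axis) of the 6 called lists (y axis, tested members in brackets) in each pool, with DMSO in grey and PCB-11 in orange. In the lens list the 3 PCB-11 pools lie at 0.34 to 0.78, and in skeletal muscle PCB-11 replicate 3 lies at 0.29 while replicates 1 and 2 lie at -0.37 and -0.46.

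The other 31 lists did not pass camera. Nearest were the circadian clock (34 tested, median -0.12, adjusted p = 0.0599), endocrine pancreas (15 tested, median 0.19, adjusted p = 0.0679) and other cytochrome P450 and pregnane X receptor targets (22 tested, median -0.19, adjusted p = 0.0798). The adjusted p of the clock list was 0.0215, 0.0434 and 0.207 without DMSO replicates 1, 2 and 3, and 0.0482, 0.0138 and 0.344 without PCB-11 replicates 1, 2 and 3. It was 0.989 with an estimated correlation and 0.0168 by fry for change in either direction. In the cytochrome list cyp2k6 rose, while the transporter gene abcb4 (-0.59 ± 0.15) and the glucuronosyltransferase gene ugt1a7 (-0.65 ± 0.17) were lower when adjusted over the list alone, both chosen after their values were seen. Glutathione and Nrf2 antioxidant genes (30 tested, median -0.03, adjusted p = 0.581), heat shock genes (22 tested, median -0.06, adjusted p = 0.17), the thyroid axis (11 tested, median 0.02, adjusted p = 0.881), cell cycle genes (26 tested, median 0.01, adjusted p = 0.837) and liver genes (31 tested, median 0.05, adjusted p = 0.751) did not pass. By fry's test for change in either direction, 8 lists passed. Smallest in adjusted p were erythrocyte markers (0.000237), endoplasmic reticulum stress (0.00901), oligodendrocyte and glia (0.00953) and hypoxia (0.0101). The others were cell cycle genes (0.0135), the clock and cytochrome P450 targets (0.0168 each) and the aryl hydrocarbon receptor list (0.0271). Leaving out a pool let some lists pass camera that had not, and 17 lists passed without PCB-11 replicate 3. Among these were neuron and synapse (median 0.275, adjusted p = 6.25e-06), oxidative phosphorylation (-0.152, adjusted p = 0.000158) and cardiac muscle (-0.266, adjusted p = 0.000462). Cytochrome P450 targets (-0.42, adjusted p = 0.000359), glutathione genes (-0.10, adjusted p = 0.0364) and endocrine pancreas (0.26, adjusted p = 0.013) passed there too. Endocrine pancreas also passed without DMSO replicate 1 (0.23, adjusted p = 0.0215), and liver genes without PCB-11 replicate 2 (0.18, adjusted p = 0.000647). Without PCB-11 replicate 2 the medians of endocrine pancreas and cytochrome P450 targets were 0.07 and -0.06. With all 6 pools, each list named here as passing on leaving out a pool had an adjusted p = 0.989 with an estimated correlation. The estrogen list had 4 tested members, too few for the test. Where other settings left enough members, camera with the preset correlation gave it an adjusted p of 0.0181 without a filter (median 0.40). The value was 0.0368 without PCB-11 replicate 2 and 0.0558 without DMSO replicate 1. The added members had failed the main expression filter, and esr1, a member that passed it, had 0.69 to 1.9 CPM per pool. An estimated correlation was not tried on this list. Median, mean and test differed in sign in 7 lists: exocrine pancreas, cell cycle, aryl hydrocarbon receptor, lipoproteins, neutrophil markers, thyroid axis and p53. With an estimated correlation 0 of the 37 lists had an unadjusted p under 0.05, and fry's directional test called 0, with 3 at an unadjusted p under 0.05 and a smallest adjusted p of 0.393.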

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

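The tests of a wrong label for PCB-11 replicate 2 and of the explanations of the lens list were chosen after the result was seen; the tests of sequencing depth and of other splits were written before.

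The share of reads outside annotated genes, which entered no comparison, was 35.0% in PCB-11 replicate 1 and 39.1% in PCB-11 replicate 2, above the highest DMSO pool (33.4%). It was 31.8% in PCB-11 replicate 3, and the groups' means were 32.5% ± 0.99 and 35.3% ± 3.67 (SD, n = 3).

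PCB-11 replicate 2, the pool with the highest such share, also stood alone on the first principal component. Its smaller total does not account for that: with every library thinned to the lowest total, its gap to the nearest pool was 0.51 of the component's range, against 0.517 before. A DMSO pool under a PCB-11 label is argued against too, since in all 7 genes called without this pool it lay beyond the 3 DMSO values in the called direction. A different makeup or stage of the animals in that pool, or a stronger response to PCB-11, may be the cause, and neither was tested.

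The lens list was higher in all 3 PCB-11 pools, and reads moving between near-identical gamma crystallin copies would leave other lens genes in place, yet the 22 lens members outside that family had a median log2 change of 0.424, and the summed gamma crystallin level was 6691 ± 624 CPM in DMSO and 9907 ± 2083 in PCB-11 (SD, n = 3). PCB-11 replicate 2 was not the whole source, as the median without it was 0.366. A larger share of whole eyes would raise the retina too, and the rod and cone list had a median of -0.0372 with an SD of 0.35 over its members (-0.172 without PCB-11 replicate 2, camera adjusted p = 0.00324, and 0.0924 without PCB-11 replicate 1). Its pool medians were -0.25 and -0.15 in PCB-11 replicates 1 and 3, but 0.299 in replicate 2 (SD 0.42 over members, lens 0.78). These medians met the bounds set against more eye tissue as the whole source, but they join opposite movements. At an unadjusted p under 0.05 in edgeR, 5 members were higher and 6 lower. Of genes chosen after their values were seen, opn1lw2 (0.58) and opn1mw2 (0.72) were higher, and rho (-0.34) and grk1a (-0.65) lower. More eye tissue therefore stays open, as the whole source or a part. An effect of PCB-11 on lens growth or lens transcripts may remain as a hypothesis, as does a difference in stage between the pools, which was not tested.

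Other splits of the 6 pools into 3 and 3 cannot decide on chance, because 10 splits never give a share under 0.1. The real split called 6 genes and the highest other 58, with 2 of the 10 splits calling at least 6. For the lists the real split called 6 and the highest other 26, and 8 of the 10 called at least 6. The split with 58 genes set DMSO replicate 1 and PCB-11 replicates 1 and 2 against the other 3 pools, the same parting as in the macrophage markers, and points to a structure of the pools that crosses the exposure. At an unadjusted p under 0.05 it had 1662 genes, the real split 1535 and the remaining splits 105 to 741. With that parting as a block, the groups differed in 7 genes, all 6 among them, and in 2 lists with the preset correlation; without the block, no list passed with an estimated correlation (adjusted p = 0.989).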

How the results depend on the processing

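Sample weights and the macrophage split as a block were added after seeing the data, as were the counts of list members on leaving out pools. The 6 called genes kept their sign in every alternative. From 6 of 12960 genes (5 higher, 1 lower), the count past the threshold moved to 110 by DESeq2 (59 and 51), 0 by limma-voom (0 and 0; 1540 at an unadjusted p under 0.05, smallest adjusted p 0.0529), 51 with sample weights (31 and 20) and 0 to 184 on leaving out each pool (0 to 55 higher, 0 to 129 lower). Genes tested numbered 12819 in DESeq2, 13012 to 13037 on leaving out a pool, 14195 without a filter and 12542 with the stricter filter. Upper quartile scaling gave 3 higher, cyp1a and nppc being lost (adjusted p = 0.0565 each), and no filter 8 higher. Other scalings, the stricter filter, plain dispersion, a 1.5-fold minimum and the macrophage block left 6 or 7 genes, all 6 among them. With the replicate number as a block, edgeR called 26 genes (20 higher, 6 lower) and camera 5 lists. Cholesterol biosynthesis was lost (camera adjusted p = 0.0678), with a median of -0.149 against -0.139 without the block. Whether the replicate numbers pair the pools stays open. Deviations of same-numbered pools correlated at 0.26, -0.15 and 0.37 across genes, and those of differently numbered pools at -0.4 to 0.23.

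Of 37 lists (38 without a filter, without DMSO replicate 1 and without PCB-11 replicate 2), 6 were called with the preset correlation, 0 with an estimated correlation, 0 by fry's directional test (8 by its test for change in either direction), 2 with the macrophage block and 4 to 17 on leaving out pools. Of 984 values of the 58 named genes under the alternatives, 859 kept sign and side of the threshold, 68 passed anew, 34 no longer passed and 23 changed sign, all of the latter in the aryl hydrocarbon receptor list. Log2 fold changes on leaving out pools were -0.088 to 0.23 for cyp1b1, -0.088 to 0.15 for cyp1d1, -0.22 to 0.39 for ahrra, -0.22 to 0.056 for nqo1, -0.22 to 0.047 for foxq1b, -0.0699 to 0.27 for ahr1b, -0.11 to 0.051 for ahr2, -0.97 to 0.19 for arnt, -0.51 to 0.0013 for arnt2 and -0.032 to 0.16 for gstp1. Reversals elsewhere were ahrra under the replicate block (0.0022) and ahrra (0.18), nqo1 (0.057), ahr1b (-0.099) and ahr2 (0.0095) under the macrophage block, and arnt (0.014) and arnt2 (0.076) with sample weights. The cause was not tested. Depth limits ahrra and arnt, with 8 to 32 counts per pool.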

Other observations

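The test of light below was written before its 3 genes were seen; the genes named here were otherwise chosen after their values were seen.

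Several macrophage transcripts were nearly missing from 3 of the 6 pools, which came from both groups. The perforin gene mpeg1.1, a standard macrophage marker, had 0.11, 0.05 and 0.37 CPM in DMSO replicate 1 and PCB-11 replicates 1 and 2, and 9.22, 5.60 and 11.9 CPM in DMSO replicates 2 and 3 and PCB-11 replicate 3. In the same order, mfap4 had 0.40, 0.21 and 0.98 against 3.23, 2.14 and 3.53 CPM, the myeloid factor gene spi1a 0.34, 0.62 and 0.92 against 4.48, 3.57 and 5.53, and ccl34b.1 0.06, 0.10 and 1.04 against 4.69, 2.96 and 4.85. The related gene mpeg1.2 did not part the pools this way, with 8.31, 9.40 and 9.58 against 10.9, 8.25 and 14.8 CPM. Neutrophil lysozyme (lyz) did not part the pools so sharply, with 29.2, 28.4 and 20.5 against 31.2, 30.8 and 44.9 CPM, while the neutrophil peroxidase gene mpx had 15.8, 12.8 and 5.71 against 26.1, 21.3 and 23.3. The genes trpa1b and p2rx3b, of touch- and pain-sensing neurons, which no list tested as a group, followed the parting. In the same order, trpa1b had 2.69, 3.25 and 2.52 against 7.50, 7.44 and 7.16 CPM, and p2rx3b 7.45, 6.77 and 5.83 against 14.8, 14.3 and 14.5. So did the xanthophore gene aox5 (5.85, 5.27 and 4.11 against 20.2, 19.0 and 16.0 CPM) and the flow-responsive factor gene klf2a (57.4, 74.8 and 58.9 against 179.7, 191.5 and 168.6 CPM). These values come with no test, and the labels name no clutch or day.

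Among 3 genes picked by their values, which no list tested as a group, all 3 PCB-11 pools lay above the DMSO pools. The zona pellucida gene zp3a.2 had 0.27 ± 0.02 CPM in DMSO and 1.98 ± 0.67 in PCB-11 (SD, n = 3), with an adjusted p of 0.0588 in edgeR, and it passed with the macrophage split as a block (0.0295), with plain library sizes (0.0346), without a filter (0.0415) and without PCB-11 replicate 2 (0.0228), all adjusted p in edgeR. It did not pass in limma-voom, with RLE or upper quartile scaling, or without DMSO replicate 1, 2 or 3 or PCB-11 replicate 1. The hatching enzyme gene he1b had 1.73 ± 0.77 and 6.49 ± 2.26 CPM (adjusted p = 0.217 in edgeR), and the yolk precursor gene vtg7 0.63 ± 0.25 and 1.65 ± 0.59 (0.317). In the eye, the rod genes rho (log2 fold change -0.34 ± 0.16), gnat1 (-0.32 ± 0.12) and grk1a (-0.65 ± 0.12) and the cone opsin kinase gene grk7a (-0.56 ± 0.12) had lower values in PCB-11, and the cone opsin genes opn1lw2 (0.58 ± 0.17) and opn1mw2 (0.72 ± 0.21) higher ones, none past the threshold over all genes in edgeR or limma-voom. DESeq2 called 2 members of the rod and cone list lower over all genes, with grk1a at an adjusted p of 0.0039, and limma with sample weights 1. The list's direction depended on single pools: its median was -0.172 without PCB-11 replicate 2 (camera adjusted p = 0.00324), and 0.0924 and 0.0867 without PCB-11 replicates 1 and 3 (0.574 and 0.681). No difference between rods and cones was tested. The growth-arrest gene cdkn1a had a lower value (-0.71 ± 0.16) and the cell death gene bbc3 a higher one (0.48 ± 0.12), both with an adjusted p of 0.0349 in edgeR when adjusted over the list alone, and of 0.281 and 0.308 over all genes; their list did not pass camera (adjusted p = 0.881).

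In 3 light-induced genes, picked by their values from a clock list that did not pass as a whole (14 of 34 members positive), values were lower in the PCB-11 pools: cry5, a photolyase gene, at -0.64 ± 0.14, cry-dash at -0.34 ± 0.10 and per2 at -0.32 ± 0.12. The clock gene per1b, which light lowers in zebrafish, was at -0.32 ± 0.10 too, which less light would not give. Less light on the PCB-11 pools before sampling could lower them, and would lower 3 other light-induced repair genes to a median of -0.2 or below. That median was -0.162 (xpc -0.44, ddb2 -0.16 and neil1 -0.10), between the bounds set for and against. No gene of this paragraph passed over all genes in edgeR (adjusted p from 0.246 for cry5 to 0.728 for neil1). Light, an effect of PCB-11 on the clock and chance differences between pools therefore cannot be told apart.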
